A study of Rattus norvegicus with 6 samples.

How the data were processed

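Gene expression was measured by RNA sequencing in 6 libraries from primary cultures of rat dorsal root ganglion cells, 3 untreated and 3 exposed to 5 mM lidocaine for 24 hours. Groups and replicate numbers were taken from the sample titles and treatment labels. The submitters' processing notes name the aligner Bowtie 0.12.2, the package DESeq2 and the rat build rn6 (Rnor_6.0), without giving the role of each. The gene annotation and the counting tool are not given in the sources used here.

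A pair of tables was used, and both held the same 2125 genes. Per the file headers these are the genes the authors called significant, and the genes left out by that selection were not analysed here. In the authors' deposited table every listed gene had an absolute log2 fold change of at least 1.00 and a p-value of at most 0.0499, and 88 p-values were deposited as 0. The first table holds normalized expression on a log2 scale, deposited by the authors as log2 of the normalized read number plus 1. After this step was undone, all 12750 values were whole multiples of a single factor per library, to within a tolerance of 0.02 reads, so the reads per gene and the relative depth of each library were recovered. The factors ranged from 0.872 to 1.18, and the step that set them is not given in the sources used here. The second table holds FPKM values (fragments scaled by gene length and library size), computed by the authors per the file headers. The log2 ratio of FPKM scaling to normalized scaling differed by 0.02 between the groups. The FPKM group value of lidocaine departed from the mean of its libraries and entered no comparison.

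The test had been planned for normalized values on a linear scale. Because the deposited values already were log2 values with a pseudocount of 1, they entered the test as deposited, and the filter was applied to the normalized reads. Genes with a mean of at least 10 normalized reads over the 6 libraries were kept, which left 1851 genes and removed 274. Lidocaine was compared with control by limma (version 3.58.1 in R 4.3.3; moderated test with a trend in the variance, two-sided, no replicate block), and p-values were adjusted by Benjamini-Hochberg over the genes kept, with a threshold of 0.05. Because the tables hold only selected genes, this adjustment covers fewer genes than were measured, and an adjustment as if over all 47357 genes of a reference gene table (assembly GRCr8) was added. Of the listed symbols, 1805 were found in that table. It was used for names and for the number of genes, and no coordinates were taken from it because its build differs from that of the files. Fold changes are on the log2(normalized reads + 1) scale, which understates the change of genes with few reads. For genes at 0 in all libraries of a group, the fold was computed against a floor of 3 counts per library, which covers counting error only.

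28 lists with 630 genes, covering cell types of the ganglion, ion channels and stress responses, were written before the data were examined, as were the test, the alternatives and the rule for naming genes. Lists with at least 3 genes kept were tested by camera (limma, preset correlation 0.01, two-sided), which sets a list against the other genes kept, with Benjamini-Hochberg adjustment over 15 lists. Camera with an estimated correlation, and fry, were run beside it. The 10 largest rises and the 10 largest falls were named among genes with a plain symbol that pass the threshold, show no overlap between the groups and have a mean of at least 100 normalized reads in the higher group. From each list, with no such minimum, up to 4 members past the threshold with the smallest adjusted p were named, and up to 2 members with the highest mean that did not pass. Scn9a, Scn10a and Scn11a were always to be named. Col5a2, Pdgfrb, Csf1 and Usp18, named because their direction turned under a rescaling, and C1qa and C1qc lie outside this rule and were chosen after their values were seen, as were the genes of the other observations. Some genes that the rule names are not reported here.

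The limma step was tested on simulated data drawn from the real means and factors with a dispersion of 0.00303, in which 200 genes were changed. Of the simulated genes 1848 passed the filter, 194 of them changed. It recovered 98.0% of 2-fold and 100% of 4-fold changes, with 8 false calls among 1654 unchanged genes. That dispersion reflects the spread between these libraries. It was the median over genes with a mean of at least 100 and was given to every gene. As many rises as falls were simulated. The deposited genes had all been selected as changed, and most were lower, so the false calls do not carry over to them. The alternatives covered the pseudocount, the filter, the scaling, the FPKM values, the trend, the threshold, a replicate block and each library left out in turn. Count models were planned for the case of whole reads but were not run. The deposited values are log2 values of selected genes only, although whole reads could be recovered from them, so the log2 scale did not prevent such models. limma with voom weights on the recovered reads was added in their place.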

Results

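Primary cultures prepared from all dorsal root ganglia of Sprague Dawley rats of 120 g were left untreated or exposed to lidocaine, a local anaesthetic that blocks voltage-gated sodium channels. The exposure was 5 mM for 24 hours, and total RNA was sequenced from 3 control and 3 lidocaine libraries. The ganglia hold the cell bodies of sensory neurons beside satellite glia, Schwann cells, fibroblasts, vascular cells and macrophages. Both deposited tables list the 2125 genes that the authors selected by fold change and p-value, so each count given here describes selected genes. Recovered reads in these genes numbered 2453051 to 3592141 per library, which is a part of each library and not its depth. Relative depth was 0.845 to 1.15 in the control and 0.997 to 1.07 in the lidocaine libraries. The labels do not say whether the replicates were separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. No pair of libraries within a group agreed within sampling noise, with a chi-square per degree of freedom of 3.32 to 8.98. Across the listed genes, Pearson's r was 0.974 to 0.988 within groups and 0.798 to 0.816 between groups. The selection of changed genes lowers the correlation between groups, and genes are not independent replicates.

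The comparison asked which transcripts differed after a day of lidocaine. The largest falls included genes of macrophages and of other non-neuronal cells, and the largest rises included genes of stress responses. C1qb, a chain of the complement component that binds immune complexes, fell from 1158 ± 14.3 normalized reads in control to 24.0 ± 4.34 in lidocaine (SD, n = 3 each), a 46.8-fold difference. Gdf15, a stress-induced cytokine, rose from 107 ± 16.2 to 1369 ± 20.6 normalized reads (SD, n = 3 each), a 12.8-fold difference. Slc7a11, the cystine and glutamate exchanger, rose 9.31-fold, and Hmox1, the heme-degrading enzyme, rose 6.28-fold.

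In the comparison of all genes kept, 1841 of 1851 passed the threshold (limma, Benjamini-Hochberg), with 572 higher and 1269 lower with lidocaine, so that 68.9% of the changed genes were lower. In the authors' deposited table, 642 of the listed genes were higher and 1483 lower. The groups did not overlap in 1822 genes (98.4%). Chance gives 10% for 3 against 3 libraries in unselected genes, which is no benchmark for genes selected on these libraries. At least 4-fold differences were seen in 94 higher and 402 lower genes. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1, so the calls rest on the spread limma shares across genes. Because the authors had chosen the genes on these same libraries, the number of calls is not independent evidence, and with adjustment as if over all 47357 reference genes 1498 calls were left. Rescaling by TMM or by the median of ratios was computed on the listed genes alone. It raised the log2 fold changes by a median over genes of 1.26 and 1.17. The splits became 631 higher and 492 lower (43.8% lower) and 592 higher and 550 lower (48.2% lower). Both methods centre the listed genes, most of which were lower.

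Of the 10 largest rises, Lypd6, a membrane-anchored modulator of Wnt signalling and nicotinic receptors, changed most, with a log2 fold change of 4.56 ± 0.14 (SE, n = 3 per group; limma, Benjamini-Hochberg adjusted p = 1.58e-09). Myo3a, an unconventional myosin, rose 17.7-fold, and Hmga2, an architectural chromatin protein, rose 12.0-fold. Stc2, a secreted glycoprotein, rose 7.93-fold and Hs3st1, a heparan sulfate sulfotransferase, 7.63-fold. Prlhr, the receptor of prolactin-releasing peptide, rose 8.02-fold. Ribc2 and Lrrc3c rose from means of 7.24 ± 4.53 and 11.3 ± 3.87 to 112 ± 10.8 and 106 ± 21.8 normalized reads (SD, n = 3 each).

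Among the 10 largest falls, Ms4a4a, a tetraspan protein of macrophages, averaged 147 ± 3.69 normalized reads in control (SD, n = 3) and was at 0 in all 3 lidocaine libraries, at least 49.9-fold lower against a floor of 3 counts per library. Sostdc1, a secreted antagonist of BMP and Wnt signalling, fell from 3735 ± 95.3 to 81.6 ± 6.89 normalized reads (SD, n = 3 each), with a log2 fold change of −5.50 ± 0.08 (SE; limma, Benjamini-Hochberg adjusted p = 4.48e-11). Slitrk6, Acta2, C3ar1, Cd163, Lamc3, Cx3cr1 and Clec4a1 averaged 126 to 266 normalized reads in control and 2.56 to 5.68 in lidocaine, and each was at 0 in at least 1 lidocaine library, so that no fold is given for them. They include smooth muscle actin (Acta2), the C3a receptor (C3ar1), the macrophage scavenger receptor Cd163, a laminin chain (Lamc3) and the fractalkine receptor Cx3cr1. Of all listed genes, 90 were at 0 in every lidocaine library and 33 in every control library. Only 17 and 7 of them passed the filter of a mean of 10 normalized reads, so most had few reads in the other group too.

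The listed markers of the non-neuronal cells of the ganglion were lower with lidocaine in each list fixed for them. Of 20 genes of macrophages and other immune cells, 16 were listed and all 16 fell, with a median log2 fold change of −2.75. Lyz2, a lysozyme, fell 6.50-fold, Csf1r, the receptor of macrophage colony-stimulating factor, fell 7.39-fold, and Mrc1, the mannose receptor, fell 4.49-fold. The list stood below the other genes by camera (limma, Benjamini-Hochberg adjusted p = 0.00462), with adjusted p = 0.278 with an estimated correlation. Of 20 genes of fibroblasts and extracellular matrix, 11 were listed and all fell (median −2.13; camera, limma, adjusted p = 0.00365, and adjusted p = 0.227 with an estimated correlation), although Col5a2 turned higher under TMM. The fibrillar collagen Col3a1 fell 8.67-fold, from 42900 ± 2048 to 4943 ± 168 normalized reads (SD, n = 3 each), and the proteoglycan Lum fell 9.10-fold. Of 16 endothelial and mural genes, 11 were listed and all fell (median −1.49; camera, limma, adjusted p = 0.0105, and adjusted p = 0.198 with an estimated correlation), although Pdgfrb turned higher under TMM and the median of ratios. They included the VEGF receptors Kdr, 7.87-fold lower, and Flt1, 4.03-fold lower. Under TMM the list medians were nearer 0, at −1.48 for macrophages, −0.86 for fibroblasts and −0.22 for endothelial and mural genes.

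Of 18 genes of Schwann cells and myelin, 10 were listed and all fell, with a median of −1.86 (camera, limma, adjusted p = 0.00403, and adjusted p = 0.143 with an estimated correlation). Mbp, a major myelin protein, fell from 24343 ± 359 to 6527 ± 139 normalized reads (SD, n = 3 each). Prx, the periaxin of myelinating Schwann cells, fell 7.75-fold, Gfap, an intermediate filament of glia, 6.71-fold, and Gldn, a ligand that clusters nodal sodium channels, 40.8-fold. Of 12 genes of satellite glia, 5 were listed and all fell, with a median of −1.85 (camera, limma, adjusted p = 0.0322, and adjusted p = 0.198 with an estimated correlation). Ptn, a secreted heparin-binding growth factor, fell 3.10-fold and Cadm2, a cell adhesion molecule, 3.61-fold. With the filter raised to a mean of 100 this call was lost (camera, limma, adjusted p = 0.0695). Under TMM the list medians were −0.61 for Schwann cells and −0.58 for satellite glia.

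Of 20 pan-neuronal genes 4 were listed, and all 4 fell, by a median log2 fold change of −1.22 that turned to 0.06 under TMM rescaling. Ina, a neuronal intermediate filament, fell 2.70-fold and Elavl2, a neuronal RNA-binding protein, 2.63-fold. Gap43, a growth cone protein, fell 2.05-fold and Elavl4 2.00-fold, and both turned higher under TMM (0.24 and 0.27 on the log2 scale) and the median of ratios (0.15 and 0.18). The list did not pass camera (limma, Benjamini-Hochberg adjusted p = 0.0677). Of 14 voltage-gated sodium channel genes only Scn7a and Scn3a were listed, and Scn9a, Scn10a and Scn11a, the channels of nociceptive neurons, were not among the listed genes. Scn7a, also a member of the Schwann cell list, fell 3.56-fold, and Scn3a fell 2.03-fold but turned higher under TMM (0.25) and the median of ratios (0.16). Of 15 calcium channel genes, Cacna2d1 and Cacna1e fell 3.10-fold and 3.29-fold and Cacnb2 rose 2.24-fold (camera, limma, adjusted p = 0.728). Of 27 nociceptor receptor and neuropeptide genes, only Ptger4, a prostaglandin E2 receptor, was listed. It fell 2.11-fold and turned higher under TMM (0.19) and the median of ratios (0.10). No member was listed of the lists of potassium and HCN channels (30 genes) or of synaptic vesicle release (23 genes).

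Genes of the ATF4 integrated stress response, the programme induced when translation initiation is restrained, were among the rises. Of its 27 genes 13 were listed, and all 13 rose, with a median log2 fold change of 1.46 and a range of 1.01 to 3.68. Chac1, a glutathione-degrading enzyme, rose from 1290.2 ± 53.2 to 6869 ± 118 normalized reads (SD, n = 3 each), and Sesn2, a stress-induced inhibitor of mTORC1, rose 3.18-fold. Gdf15 and Slc7a11 belong to this list as well. The list stood above the other genes by camera (limma, Benjamini-Hochberg adjusted p = 1.05e-07), with adjusted p = 0.133 with an estimated correlation. Of 22 unfolded protein response genes only Herpud1 was listed, and it rose 2.76-fold. Of 22 NRF2 antioxidant genes, Hmox1 and Slc7a11 were listed. Hmox1 rose from 9857 ± 670.4 to 61809 ± 1806 normalized reads (SD, n = 3 each). Of 22 heat shock genes only Cryab, a small heat shock protein, was listed, and it rose 3.70-fold. Of 26 p53 target and apoptosis genes only Mdm2, the ubiquitin ligase of p53, was listed, and it rose 2.03-fold.

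All 6 listed of 24 cholesterol biosynthesis genes rose (median 1.14; camera, limma, adjusted p = 0.000384, and adjusted p = 0.133 with an estimated correlation). Insig1, a sterol-sensing regulator that retains SREBP in the endoplasmic reticulum, rose 4.24-fold, and Sqle, the squalene epoxidase, rose 2.45-fold. All 6 listed of 25 glycolysis and hypoxia genes rose (median 1.28; camera, limma, adjusted p = 0.000293, and adjusted p = 0.198 with an estimated correlation). Hk2, a hexokinase, rose 3.40-fold, Slc2a1, a glucose transporter, 2.28-fold, and Adm, the hypoxia-induced peptide adrenomedullin, 3.96-fold. All 3 listed of 27 lysosome genes rose (median 1.48; camera, limma, adjusted p = 0.0134, and adjusted p = 0.198 with an estimated correlation). These were Gpnmb (2.80-fold), Neu1 (2.53-fold) and Atp6v0d2, which averaged 3.51 normalized reads in control and 36.6 in lidocaine. Of 22 cell cycle genes Mcm2 and Mcm6, parts of the replicative helicase, were listed and rose 2.32-fold and 2.22-fold. No member was listed of the lists of autophagy (22 genes), the nuclear-encoded respiratory chain (35 genes), mitochondrially encoded transcripts (13 genes) or cytosolic ribosomal proteins (30 genes).

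Of 25 immediate early genes 9 were listed, of which 7 rose and 2 fell (median 1.30; camera, limma, adjusted p = 0.00462, and adjusted p = 0.198 with an estimated correlation). Dusp1, a MAP kinase phosphatase, rose 3.69-fold and Fosl1, a Fos-family transcription factor, 3.02-fold. Of 30 inflammatory cytokines and NF-kB targets 16 were listed, of which 6 rose and 10 fell. Il6 and Lcn2 rose 2.94-fold and 2.77-fold, whereas the chemokine Ccl2 fell 2.90-fold and the adhesion molecule Vcam1 15.2-fold. The median of this list was −1.45 and its mean −0.81, whereas camera placed it above the other genes, most of which were lower, without passing (limma, adjusted p = 0.728); Csf1 turned higher under TMM and the median of ratios. Of 24 interferon response genes 7 were listed and all 7 fell (median −1.89), although Usp18 turned higher under TMM and the median of ratios. Mx2 and Mx1, antiviral GTPases, fell 5.00-fold and 3.94-fold, but the list did not pass camera (limma, adjusted p = 0.0548, and adjusted p = 0.278 with an estimated correlation). It did pass under TMM (adjusted p = 0.0403), under the median of ratios (0.0391), without control replicate 2 (0.0492) and without lidocaine replicate 1 (0.0493; limma, Benjamini-Hochberg). Of 28 axon injury and regeneration genes 10 were listed, of which 9 fell and Il6 rose (median −1.72; camera, limma, adjusted p = 0.0772), although Csf1 and Gap43 turned higher under TMM and the median of ratios. Sox11, a transcription factor of regenerating neurons, fell 3.48-fold, and Ecel1, an endopeptidase induced by nerve injury, fell 2.64-fold.

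For each list, the number of members past the threshold adjusted over the list alone was the same as that over all genes tested. The lists were fixed in advance, but their listed members had been chosen by the authors on these libraries, so the counts of changed members are not independent evidence. The tables give no value for the members that are not listed. Of the 15 lists tested, 10 passed camera with the preset correlation and 0 with an estimated correlation (limma, Benjamini-Hochberg), where 3 had an unadjusted p under 0.05. All 15 passed fry, which tests whether the members move one way on balance and does not set a list against other genes. Every member had been selected as changed on these libraries, which favours passing fry in advance, so no conclusion is drawn from these passes.

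**Figure D1:**
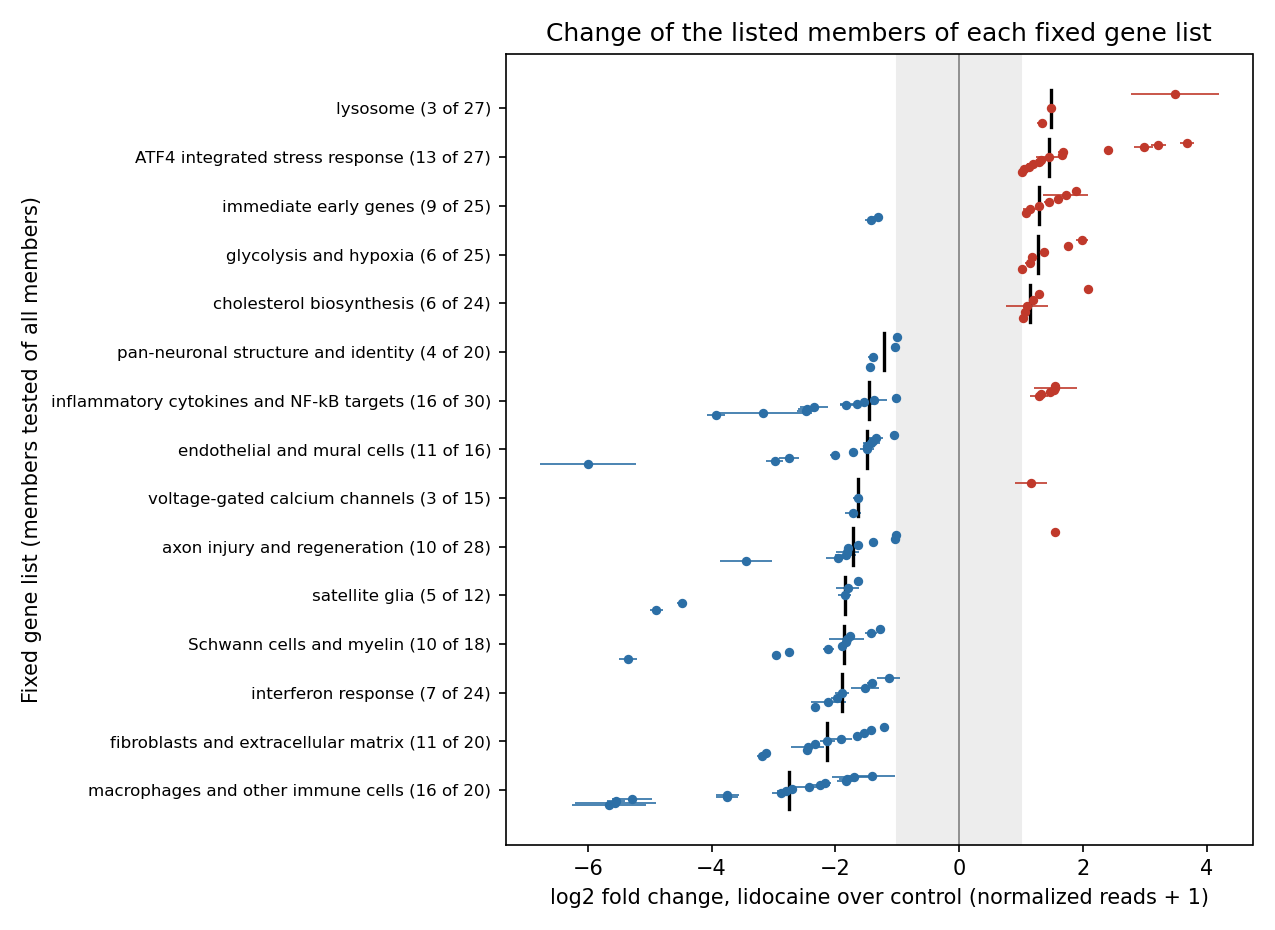
Log2 fold change (lidocaine over control, normalized reads + 1) of each tested member of the 15 fixed lists with at least 3 such members; points are fitted values with their standard error, black lines are list medians and the shaded band, from which the authors' selection left almost no gene, spans 1 log2 unit either side of 0. The medians run from −2.75 (macrophages and other immune cells) to 1.48 (lysosome), and under TMM that of the pan-neuronal list turned from −1.22 to 0.06 while Col5a2, Pdgfrb, Csf1, Usp18, Gap43 and Elavl4 turned higher.

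**Figure D2:**
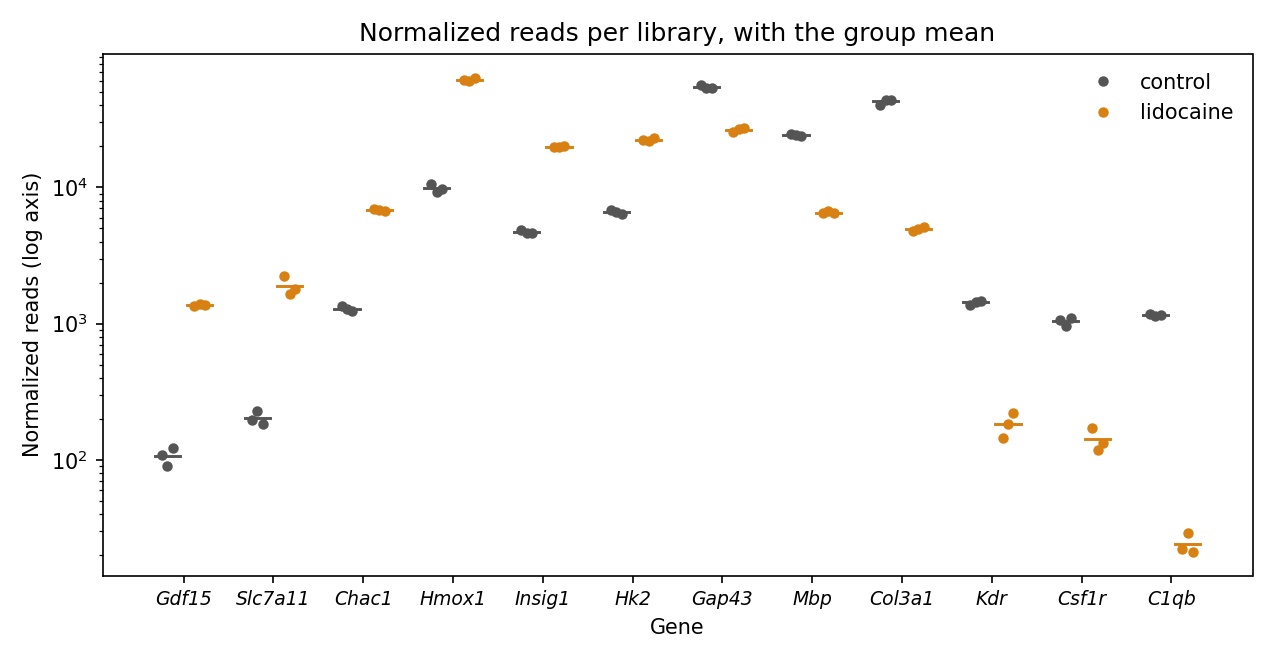
Normalized reads (log axis) of 12 named genes in each of the 3 control and 3 lidocaine libraries; points are libraries and lines are group means. The groups do not overlap in any of these genes, with C1qb at 1158 in control and 24.0 in lidocaine and Hmox1 at 9857 and 61809, while Gap43, lower here, turned higher under TMM (0.24 on the log2 scale) and the median of ratios (0.15).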

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

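All the tests in this part were chosen after the results they bear on had been seen.

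In the FPKM table the authors' group value of lidocaine, which enters no comparison, exceeded the mean of the 3 lidocaine libraries in 2109 of 2125 genes and equalled it in 16, whereas the control group value equalled the control mean in all 2125. The best linear combination of the 6 library columns gave the group value to within 1% in only 4.28% of genes, which argues against other proportions of these columns, and the correlation across genes was 0.962 in place and −0.00858 after a shift by 1 row, which argues against rows out of order. Whether further libraries were summed into the value before division by 3 stays open: 0 genes had 3 times the group value below the sum of the 3 columns, but this follows from the group value never lying below the mean. The remainder of 3 times the group value minus that sum was divided by 3. It then lay between the control and lidocaine means in 1785 genes (84%). It correlated with control at 0.985 and with lidocaine at 0.889 across genes. No biological explanation was tested.

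All 48 listed markers of macrophages, fibroblasts, vascular cells and Schwann cells were lower with lidocaine, although Col5a2 and Pdgfrb turned higher under TMM. The share of falls was 68.1% among the other 1803 genes. With each list set against the other genes, the adjusted p was 0.0157 for macrophages, 0.0467 for fibroblasts, 0.0467 for vascular cells and 0.0613 for Schwann cells (two-sided Fisher's exact test, Benjamini-Hochberg over the 15 lists tested, genes counted as independent). Satellite glia, lower in 5 of 5 listed genes, were at an adjusted p of 0.384 in the same Fisher's exact test. Counted this way, macrophages, fibroblasts and vascular cells passed, and Schwann cells, where 10 of 10 lower were too few to pass, did not. Markers of a cell type may change together, which this test ignores. By camera with an estimated correlation none of these lists passed (limma, adjusted p = 0.278, 0.227, 0.198 and 0.143 in the same order). Whether the authors' selection of genes was the whole cause therefore stays open for each of them. The relative depth of the lidocaine libraries reached 1.07 and lay within the range of the controls. It is the inverse of the factors already applied to these values, and the step that set them is not given. The total depth in reads is unknown as well, but FPKM values are scaled by library size. Their median ratio to recovered reads, relative to control replicate 1, was 1, 1.37 and 1.16 in control. In lidocaine it was 1.17, 1.10 and 1.17, within the control range. This argues against a difference in that library size between the groups, though the reads it counted are not given. A loss of macrophages that took every macrophage transcript down alike is argued against by the SD of 1.51 between the log2 fold changes of that list, whose median standard error was 0.165: −3.75 for C1qa, −5.55 for C1qb and −5.28 for C1qc, so loss combined with altered expression may remain.

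The 13 listed ATF4 genes were all higher with lidocaine. A higher share of neurons in the lidocaine libraries would raise pan-neuronal genes too, but the median log2 fold change of the 4 listed was −1.22 (median SE 0.06). Under TMM rescaling it was 0.06, against 2.71 for the ATF4 list. The 16 pan-neuronal genes that are not listed have no value here, so the 4 selected genes do not settle the share of neurons. A scaling factor moves every gene alike, and as the whole cause it is argued against by the SD of 0.909 between the log2 fold changes of the ATF4 list, whose median standard error was 0.07. A shift shared by all members leaves this SD unchanged and stays open. The list median was 1.33 to 2.71 under the other scalings tried, but these do not test such a shift. TMM, the median of ratios and quantile normalization each raised the median of all genes, most of which were lower. The FPKM scaling differed from the normalized scaling by only 0.02 between the groups on the log2 scale. The FPKM fit gave the 1.33, with a pseudocount of 1 added to each FPKM value, which understates changes at low FPKM. This lower median is therefore not an effect of scaling alone. An induction of the ATF4 genes by lidocaine may be a hypothesis to follow, found and tested on the same data. Which cells of the culture carried it was not tested.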

How the results depend on the processing

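The adjustment over the reference gene table, voom on recovered reads, and the lists under FPKM and the median of ratios were chosen after the data were seen. Among the alternatives fixed in advance, edgeR and DESeq2 were not run, although whole reads could be recovered from the deposited log2 values of selected genes. The 1841 changed genes (572 higher, 1269 lower) became 1068 (381, 687) with a minimum mean of 100, where fewer genes were tested. They became 1123 (492 lower) with TMM and 1142 (550 lower) with the median of ratios, both of which centre a table of mostly lower genes. Other settings gave 1462 (quantile normalization) to 2101 (no filter). Both 1498 (reference adjustment) and 1693 (adjusted p under 0.01) rest on a stricter threshold, and FPKM gave 1830 and voom 1835. The median over genes of the shift in log2 fold change was 0.77 with quantile normalization and 0.38 with FPKM. The median log2 fold change itself went from −1.25 to −0.49 with quantile normalization and to −0.45 with FPKM. The FPKM fit used log2(FPKM + 1), which understates changes at low FPKM. With each library left out in turn the counts were 1767 to 1806 changed, 558 to 564 higher and 1204 to 1248 lower. The log2 fold changes of Scn3a, Ptger4, Gap43 and Elavl4 reversed to 0.25, 0.19, 0.24 and 0.27 under TMM and to 0.16, 0.10, 0.15 and 0.18 under the median of ratios. For the named genes, 1454 values under the alternatives kept direction and side of the threshold, 4 lost the threshold and those 8 reversed. Of the values that lost the threshold, 3 were under TMM and 1 under quantile normalization. Of 10 lists called, 0 were called with an estimated correlation, and 10 to 11 with a library left out. With a minimum mean of 100 the satellite glia list lost its call (camera, limma, adjusted p = 0.0695). The lysosome list then kept too few genes to be tested. fry called all 15 and placed the inflammatory list lower (limma, adjusted p = 0.000468), since fry does not set a list against other genes. The selection of the members on these libraries favours such calls, so no conclusion is drawn from them. The interferon list (camera, limma, adjusted p = 0.0548) passed without control replicate 2 (0.0492) and without lidocaine replicate 1 (0.0493), as well as under TMM (0.0403) and the median of ratios (0.0391). By camera with an estimated correlation its adjusted p was 0.278. The adjusted p of fry, which asks a different question and is favoured by the selection of the members, was 1.27e-05. The replicate numbers do not pair the samples: deviations of same-numbered libraries correlated at −0.03, 0.01 and 0.06, and 2 of 6 libraries matched their own number best. The replicate block gave 1842 changed genes (574 higher, 1268 lower) and an interferon list at an adjusted p of 0.0485 (limma), and changed no other list call. Of 10 splits of the 6 libraries, 1, the real grouping, gave as many as 1841 genes, and the highest other gave 0 (limma; 13 to 22 genes at an unadjusted p under 0.05 in the other splits). Too few splits exist for a share under 0.05. The listed genes had also been selected on the real grouping, which favours it over every other split, so no conclusion is drawn from this comparison. The total depth of the libraries is unknown, and genes with few reads have folds that move with the pseudocount.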

Other observations

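The genes, the pathways and the test in this part were chosen after the values were seen. MHC class II is the route by which macrophages and related cells show peptides to helper T cells. Cd74, its invariant chain, averaged 413 ± 27.0 normalized reads in control and 58.9 ± 7.39 in lidocaine (SD, n = 3 each), and RT1-Da fell from 143 ± 39.0 to 11.3 ± 6.38. RT1-DMa fell from 219.8 ± 9.99 to 94.5 ± 23.2 (log2 fold change −1.24, which turned to 0.03 under TMM). RT1 genes belong to a family of related genes, so the values of its single members may be uncertain. Among the pathway names in the authors' deposited table, 120 with at least 10 genes kept were tested for the balance of falls and rises against the other annotated genes (two-sided Fisher's exact test, Benjamini-Hochberg over 120). Of these, 4 passed: systemic lupus erythematosus, lower in 24 of 24 genes, phagosome, in 30 of 31, and Staphylococcus aureus infection, in 23 of 23 (adjusted p = 0.0121 each), and extracellular matrix receptor interaction, in 25 of 26 (adjusted p = 0.0493). With a symbol that stands under several identifiers counted as 1 gene, the same 4 of 118 passed (adjusted p = 0.0207 for the first 3 and 0.0475 for extracellular matrix receptor interaction). The pathways named for lupus, phagosome and Staphylococcus infection all hold class II RT1 genes. The pathway of antigen processing and presentation, lower in 14 of 14, did not pass (adjusted p = 0.133). Under TMM rescaling some members turned higher, and the numbers lower were 21, 24, 20, 23 and 13 in the same order. These pathways share genes with the fixed lists.

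Against the falls of macrophage genes, Mmp12, known as macrophage elastase, was higher with lidocaine, at 7704 ± 297 normalized reads against 1266 ± 128 in control (SD, n = 3 each). Gdnf, a survival factor of sensory neurons, was at 882 ± 73.2 against 223 ± 2.52, and Ccnd1, a cyclin of the G1 phase, at 31174 ± 3106 against 4242 ± 70.0. Scd, which desaturates fatty acids, was at 41763 ± 2969 against 8139 ± 35.2. Hspa2, a heat shock protein, was at 2629, 2796 and 59.2 normalized reads in lidocaine replicates 1, 2 and 3, against 11453 ± 385 in control (SD, n = 3). Tagln, a smooth muscle protein, was at 472, 88.9 and 73.3 in the same libraries, against 2667 ± 471 in control, so the odd library differed between these genes.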
